A study of Homo sapiens with 12 samples.

How the data were processed

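RNA-seq was done on 12 libraries of the prostate cancer line DU145, 2 biological replicates of each of 6 lines, per the labels. The labels give the line, the guide, the clone and the batch of each library, and the replicate number equals the batch number. Cells grew in RPMI medium with 10% fetal bovine serum, RNA was taken with TRIzol and a column, and libraries were made from 160 ng of RNA by SMARTScribe reverse transcription, amplification with Advantage 2 polymerase and tagmentation, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.6.1d, DESeq2 and the genome build GRCh38. The counting tool, its strand setting and the annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared between them.

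The authors deposited 1 table of 56832 genes with a TPM value per library. TPM divides by transcript length and scales each library to 1000000, so it keeps no depth, and the depth of each library is unknown. For 15140 genes the same table holds the authors' comparison, with the columns DESeq2 writes, per the file headers: a mean signal of normalized counts, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted p-value, all computed by the authors. How the authors set up that comparison is not given in the sources used here. The symbols are older ones (DDX58, HIST1H1C), and gene positions were taken from GENCODE release 29 on GRCh38 by symbol, which gave a position for 69.1% of the genes kept.

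The design had assumed counts, with a count test on sums per line. As the values are TPM, the fallback written with it before the data were examined was used: limma 3.58.1 in R 4.3.3 on the mean over the 2 libraries of log2(TPM + 1) per line, 3 knockout lines against 3 RAC1-positive lines, with moderated variances that follow mean expression and Benjamini-Hochberg adjustment at 0.05. Genes needed a mean of at least 1 TPM in either genotype, which left 17367 genes. This filter was chosen once the unit was known. Differences are on the log2(TPM + 1) scale, which understates the change of genes near or below 1 TPM. Contrasts of single clones and of RAC1-positive lines used all 12 libraries in 1 limma fit with a mean per line, so their p-values measure the spread between the 2 libraries of a line. RAC1 was also compared by an exact permutation test of the line means.

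Named genes followed a rule written before the data were examined: RAC1, RAC2, RAC3, RHOG, CDC42, VAV2, VAV3 and EGFR, then 12 genes per direction past the threshold with the lines of the genotypes apart and a level condition, filled by smallest p where fewer passed. Per gene list up to 4 members past the threshold or the 2 with the smallest p could be named, and per contrast and direction 3 genes. The level condition of 50 normalized counts was applied to the authors' mean signal shared out by the TPM of each genotype. In all 35 gene lists and 7 sets of cell type markers were fixed, symbols were matched as written, and lists with at least 3 members above the filter were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation, and fry. Members were also adjusted over the list alone. The result of 1 of the tested lists is not reported here.

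Replicate numbers mark a shared batch per the labels, so a fit with the replicate number as a block was run beside each result. The correlation of same-numbered deviations over 15 pairs of lines ran from -0.13 to 0.30 with a median of 0.026, and 2 pairs were over 0.1. None of 66 pairs of libraries held identical values, and the highest correlation of 2 libraries was 0.964.

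The scripts were tested on simulated data of 17367 genes with 200 changed genes in each of 5 simulations. For 3 lines against 3 lines, limma recovered 11.6% of genes changed 1.5-fold, 41.5% of those changed 2-fold and 81.8% of those changed 4-fold. For 12 libraries by genotype it recovered 34.9%, 69.9% and 90.9%, and for 1 knockout clone against the RAC1-positive lines 6.57%, 30.7% and 74.2%. Unchanged genes were called in 0.0315% to 0.0617% of cases. Apart from the set changes the simulated lines shared 1 mean per gene, and noise followed the spread between libraries of a line. Differences between lines of 1 genotype were thus left out. Changed genes were drawn only from those at 5 TPM or more by the mean log2(TPM + 1) of the RAC1-positive libraries. The shares recovered in real lines may be lower.

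Alternatives covered the unit of replication, the replicate block, median-of-ratios and upper quartile scaling, the level filter, the pseudocount (0.1 and 5), each batch alone, each line or library left out, and for lists the correlation, the test and the symbols. Differences between genotypes were also taken within each batch, and their change between batches was tested in limma on the difference of the 2 libraries of each line. The overlap of calls between clones was set against 20 simulations of unchanged clones with the same controls. Count-based alternatives in the plan were replaced by limma on log2 TPM, and the count test on line sums was not run. Positions were analysed over 6812 protein-coding genes of at least 5 TPM, with 95% intervals of set medians from 2000 bootstrap resamples of genes, which are not independent, so these intervals are too narrow.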

Results

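RNA from DU145 cells, an established human prostate cancer line, was sequenced in 12 libraries from 6 cell lines grown in medium with 10% fetal bovine serum. Of these lines 3 carried RAC1: the parental line and 2 clones made with a non-targeting guide, sgNTC clones 1 and 2. The other 3 were RAC1 knockout clones made by Cas9. Of these, sgRAC1 clone 1 was made with the guide sgRAC1_1 and clones 2 and 3 with the guide sgRAC1_2. Each line had 2 biological replicates, and the replicate number was also the batch. RAC1 encodes a small GTPase that drives actin-based protrusion. The series title sets the work in the response of RAC1 to the growth factor receptor EGFR through the exchange factor VAV2. Values were transcript abundances (TPM), which sum to 1000000 in every library, so the sequencing depth of each library is unknown. The number of genes listed above 0 was 13608 in sgNTC clone 2 replicate 1 and 20470 to 25156 in the other libraries. The median correlation of that library with the others was 0.872, against 0.936 to 0.954 elsewhere.

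RAC1 itself was measured first. Its transcript stood at 46.2 ± 9.14 TPM in the knockout clones and 172 ± 4.60 TPM in the RAC1-positive lines (SD, n = 3 lines each). The knockout clones thus kept 26.9% of the level of the RAC1-positive lines. The 6 knockout libraries lay between 36.5 and 59.2 TPM and the 6 RAC1-positive libraries between 149 and 202 TPM. RAC1 (chromosome 7, 6374523 to 6403977, GRCh38) fell by 1.89 on the log2(TPM + 1) scale (SE 0.14, limma adjusted p = 0.0467), and all 3 knockout lines were below all 3 RAC1-positive lines. A two-sided exact permutation test of the line means gave p = 0.10, the smallest that 3 lines against 3 can give. Within batch 1 the difference was -1.93 (limma adjusted p = 0.128) and within batch 2 it was -1.84 (limma adjusted p = 0.0414). The limma adjusted p stayed under 0.05 without sgRAC1 clone 2 (0.0201), sgNTC clone 1 replicate 2 (0.0363), sgNTC clone 2 replicate 1 (0.0276) or sgRAC1 clone 2 replicate 1 (0.0371). It was above 0.05 without any 1 of the other 5 lines or 9 libraries, up to 0.370 without sgRAC1 clone 3. The call was also lost under median-of-ratios scaling (limma adjusted p = 0.0578), upper quartile scaling (0.0605), no level filter (0.172) and a pseudocount of 0.1 (0.0857).

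**Figure D1:**
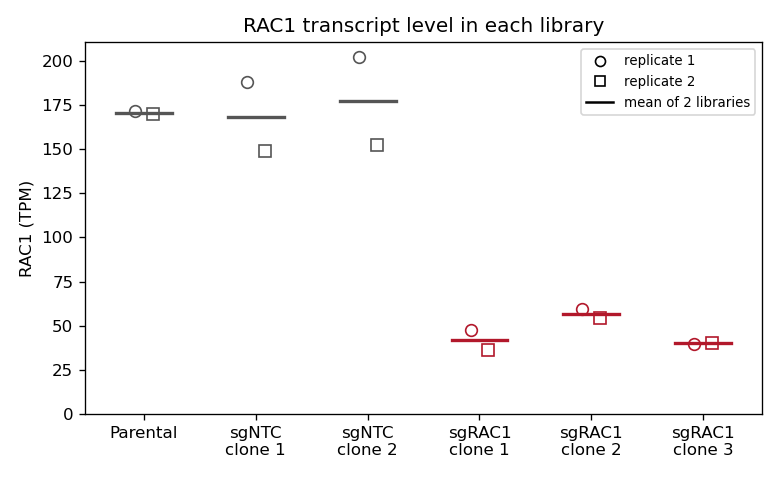
RAC1 level in TPM in each library of the 6 lines, with circles for replicate 1, squares for replicate 2 and a bar for the mean of 2 libraries. The knockout libraries lie between 36.5 and 59.2 TPM and the RAC1-positive libraries between 149 and 202 TPM.

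The central comparison asked which transcripts differ between the 3 knockout clones and the 3 RAC1-positive lines. RAC1 was the only gene of 17367 to pass, with 0 genes higher and 1 lower at a limma adjusted p of 0.05. The count was 0 under each setting that ended the RAC1 call, 2 at a pseudocount of 5 and 3 with a filter of 5 TPM. At the same time 2256 genes had an unadjusted p under 0.05 against 868 expected by chance. The tetraspanin gene TSPAN7 was at 18.4 ± 3.97 TPM in the knockout lines and 0.968 ± 0.62 TPM in the RAC1-positive lines (SD, n = 3 lines), a log2 difference of 3.35 (SE 0.30) that missed the threshold (limma adjusted p = 0.0710). SAT1, which encodes the spermidine/spermine acetyltransferase of polyamine breakdown, was at 499 ± 116 against 152 ± 24.9 TPM (log2 difference 1.70, SE 0.18, limma adjusted p = 0.0982). SMS, the spermine synthase gene of polyamine synthesis, was at 336 ± 23.4 against 509 ± 30.5 TPM (log2 difference -0.61, SE 0.09, limma adjusted p = 0.143). TSPAN7, SAT1 and SMS were named by smallest p among genes with all 3 knockout lines on the same side of all 3 RAC1-positive lines. Such separation was found for 3557 genes, 20.5% of those tested, where chance gives 10%. Of these genes 2078 were higher and 1479 lower in the knockout lines.

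None of the genes that follow passed at the line level, and each is given with its log2 difference and limma adjusted p. They were chosen by smallest p with all 3 knockout lines on one side of the RAC1-positive lines. Among the higher genes, LYN, a Src family kinase, was at 31.6 ± 1.72 against 14.5 ± 0.72 TPM (1.08, adjusted p = 0.0982, limma). GLIPR1 was at 7.54 ± 2.08 against 0.713 ± 0.23 TPM (2.29, adjusted p = 0.0982, limma). The adhesion gene MPZL2 was at 190.0 ± 80.03 against 41.1 ± 9.22 TPM (2.15). LAMB1, a laminin chain of basement membrane, was at 28.4 ± 1.05 against 12.6 ± 1.71 TPM (1.11), and C9orf84 at 16.3 ± 1.60 against 6.19 ± 0.53 TPM (1.27). The immunoproteasome subunit gene PSMB8 was at 57.2 ± 15.7 against 18.4 ± 0.65 TPM (1.55). DDX58, which encodes the viral RNA sensor RIG-I, was at 13.1 ± 1.56 against 4.68 ± 0.84 TPM (1.32). The log2 differences of CPM, SEL1L3 and GCNT3 were 0.85, 1.10 and 1.02. Limma adjusted p for these 12 genes, TSPAN7 and SAT1 included, ran from 0.0710 to 0.143. Among the lower genes, the kinase gene PLK2 was at 27.3 ± 3.88 against 66.9 ± 20.9 TPM (-1.36). DIMT1, an rRNA methyltransferase gene, was at 54.2 ± 1.92 against 119 ± 27.5 TPM (-1.15), and the adhesion gene CADM1 at 4.43 ± 0.49 against 10.1 ± 0.69 TPM (-1.03). MCM4, a subunit of the replicative helicase, was at 79.2 ± 2.35 against 121 ± 13.3 TPM (-0.68). CRY1, a repressor of the circadian clock, was at 4.90 ± 0.70 against 9.91 ± 0.47 TPM (-0.90). The log2 differences of FJX1, DNAJC2, RFLNB, FTSJ2 and the linker histone gene HIST1H1E were -0.96, -0.86, -0.72, -0.69 and -0.66. Limma adjusted p was 0.143 for all 11 lower genes that follow RAC1, SMS included. The difference was over 1.5 times as large in batch 1 as in batch 2 for 6 of the 12 lower genes: MCM4 (-1.17 and -0.19), PLK2 (-1.91 and -0.81), DIMT1 (-1.51 and -0.80), CRY1 (-1.33 and -0.47), FJX1 (-1.27 and -0.64) and SMS (-0.80 and -0.42). MCM4 stood at 51.1 to 56.0 TPM in the knockout libraries of batch 1 and at 102 to 107 TPM in those of batch 2, a split that the SD over line means leaves out. Of the 12 higher genes CPM (0.67 and 1.03) and SEL1L3 (0.86 and 1.35) had a difference over 1.5 times as large in batch 2. A limma test of the change between batches, added after these values were seen, called 0 of 17367 genes (724 at unadjusted p under 0.05), and its adjusted p for MCM4 was 0.912. On simulated data of as many genes that test recovered 0% of 200 genes changed 4-fold between batches, so its count of 0 does not show that the batches were alike.

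The count of genes depended on what served as the replicate. With the 12 libraries as separate samples and the line as a random block, 369 genes passed in limma, 294 higher and 75 lower in the knockout clones, and 620 (466 higher, 154 lower) without sgNTC clone 2 replicate 1. With the replicate number added as a block 320 passed. TSPAN7, SAT1 and PSMB8 were among the 369, at adjusted p of 2.25e-05, 2.17e-04 and 7.98e-04 in limma. SMS was at 0.0122, while MCM4 did not pass (0.115). Those p-values rest on a within-line correlation estimated at -0.03, which treats libraries of 1 line as independent. With 1 value per line, limma called 0 genes in batch 1 alone and 33 in batch 2 alone (21 higher, 12 lower). It called 21 without sgNTC clone 2 replicate 1 (13 higher, 8 lower) and 3 without sgNTC clone 1 replicate 2. The count was 1 without sgRAC1 clone 2 or its replicate 1, and 0 without any other single line or library.

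The authors' deposited table holds a comparison of 15140 genes. At adjusted p 0.05 there were 860 genes higher and 614 lower in the authors' deposited table. RAC1 had a log2 fold change of -1.90 in the authors' deposited table (adjusted p = 9.26e-60). Of the 1474 genes called in the authors' deposited table, 1453 were tested here, all 1453 had the same direction, and 1261 had the knockout lines apart from the RAC1-positive lines. Of the 369 genes called with the line as a random block in limma, 358 were in the authors' deposited table and 354 were also called there. The authors' comparison and the TPM values come from the same series, so these shared directions and calls are not independent support.

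Genes tied to RAC1 signalling by the study title or by family were examined next. RAC2, the paralog best known from blood cells, was at 7.01 ± 1.34 TPM in the knockout lines and 3.47 ± 0.78 TPM in the RAC1-positive lines (SD, n = 3 lines; log2 difference 0.85, SE 0.21). It missed the threshold per line (limma adjusted p = 0.204) and passed with the line as a random block (limma adjusted p = 0.0189). In the authors' deposited table the log2 fold change of RAC2 was 0.88 (adjusted p = 0.00697). VAV2 was at 2.41 ± 0.89 against 2.65 ± 0.64 TPM and EGFR at 17.7 ± 3.997 against 15.1 ± 1.51 TPM. RHOG was at 19.3 ± 1.22 against 20.2 ± 3.59 TPM and CDC42 at 207 ± 11.03 against 219 ± 10.7 TPM. None of these 4 differences passed (limma adjusted p = 0.876 for VAV2, 0.679 for EGFR, 0.941 for RHOG and 0.723 for CDC42). The sign for VAV2, RHOG and CDC42 turned within 1 batch. RAC3 was below the level filter, at 0 to 2.24 TPM, and VAV3 was listed at 0 in every library.

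Of 34 gene lists fixed before the data were examined and tested with limma's camera at a preset correlation, 14 passed, 9 higher and 5 lower in the knockout lines. Other splits of the 6 lines into 3 against 3, with both genotypes on each side, passed 0 to 13 lists in the same test. The correlation estimated within the 14 lists ran from 0.056 to 0.68, against the preset 0.01. A call at the preset correlation thus does not by itself point to the genotype. None of the 14 passed with an estimated correlation (lowest adjusted p = 0.435) or with fry (lowest adjusted p = 0.0594), which tests whether the genes of a list move, on balance, one way. With the 12 libraries and the replicate number as a block, camera passed 14 lists, fry 13 and the estimated correlation 0. That fit held no term for the line, so the 2 libraries of a line counted as independent samples of the genotype. The 13 lists of fry were 8 of the 14 and 5 others. The ribosomal protein, DNA replication, mitosis, oxidative phosphorylation, YAP and TAZ and cholesterol lists missed its threshold there (fry in limma, adjusted p from 0.0576 to 0.336). No member of these lists passed over all genes tested, so members are given by value. Each list median below kept its sign under both other scalings.

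Interferon stimulated genes rose as a list, with a median log2 difference of 0.90 over 25 members (camera in limma, adjusted p = 1.5e-10, and adjusted p = 0.435 with an estimated correlation). Of these members 24 were higher, 15 had all knockout lines above all RAC1-positive lines, and 13 passed when adjusted over the list alone. DDX58 (values above) and ISG20, an exonuclease gene at 8.95 ± 2.03 against 3.29 ± 0.28 TPM, had the smallest p, both at a limma adjusted p of 0.143. The median of the list relative to the RAC1-positive lines was 0.75 in sgRAC1 clone 1, 0.54 in clone 2 and 1.52 in clone 3, and between -0.15 and 0.10 in the RAC1-positive lines. MHC class I and antigen processing genes also rose as a list, by a median of 0.63 over 16 members (camera in limma, adjusted p = 2.1e-07, and adjusted p = 0.435 with an estimated correlation). Of its members 10 passed when adjusted over the list alone. B2M, the light chain of MHC class I, was at 1367 ± 185 against 856 ± 69.7 TPM and PSMB8 at the level given above. Of 23 interferon stimulated and 16 MHC class I genes, 13 and 10 were higher at adjusted p 0.05 in the authors' deposited table and none was lower.

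Replication-dependent histone genes rose as a list of 5 members (median 1.22, camera in limma, adjusted p = 4.5e-06, and adjusted p = 0.435 with an estimated correlation). All 5 passed when adjusted over the list alone. Among them HIST1H1C was at 799 ± 243 against 332 ± 53.2 TPM and HIST1H2BK at 447 ± 80.2 against 259 ± 21.4 TPM. With older symbols matched as well the list had 18 members, a choice made after the data were seen, and adjusted p was 0.00273 in limma's camera and 0.435 with an estimated correlation. The linker histone gene HIST1H1E was lower (-0.66). Reads of near-identical histone genes, like those of the HLA genes, can be split between copies in ways the sources used here do not state.

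Lists on adhesion and the cytoskeleton came next. Matrix proteases and inhibitors rose as a list (median 0.30 over 18 members, camera in limma, adjusted p = 3.4e-04, and adjusted p = 0.435 with an estimated correlation). Of its members 3 passed when adjusted over the list alone, and MMP24 was at 7.05 ± 2.71 against 1.99 ± 0.75 TPM. SRF and MRTF target genes, which respond to the actin pool, rose as a list (median 0.28 over 25 members, camera in limma, adjusted p = 3.4e-04, and adjusted p = 0.435 with an estimated correlation). Of its members 9 passed when adjusted over the list alone. The PDZ and LIM domain gene PDLIM5 was at 49.8 ± 6.45 against 27.4 ± 2.00 TPM and the vinculin gene VCL at 78.1 ± 12.3 against 49.0 ± 4.47 TPM. Epithelial junction and keratin genes rose as a list (median 0.34 over 24 members, camera in limma, adjusted p = 3.5e-04, and adjusted p = 0.435 with an estimated correlation). Of its members 8 passed when adjusted over the list alone. The plakoglobin gene JUP was at 3.38 ± 0.54 against 0.745 ± 0.28 TPM and the protease inhibitor gene SPINT1 at 3.44 ± 0.76 against 0.583 ± 0.38 TPM. YAP and TAZ target genes fell as a list (median -0.20 over 21 members, camera in limma, adjusted p = 0.0313, and adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone, 1 member was higher and 3 lower, with FJX1 among the lower and MYOF higher at 85.2 ± 11.6 against 57.9 ± 5.98 TPM. With older symbols matched as well, a choice made after the data were seen, the list had 23 members and was also lower. Adjusted p was then 0.00495 in limma's camera and 0.435 with an estimated correlation.

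Metabolic and redox lists moved upward, apart from nuclear genes of oxidative phosphorylation. NRF2 target genes rose as a list (median 0.20 over 30 members, camera in limma, adjusted p = 0.0030, and adjusted p = 0.512 with an estimated correlation). Higher members were 9 and lower members 1 when adjusted over the list alone. The peroxidase gene GPX2 was at 6.21 ± 3.91 against 0.239 ± 0.22 TPM and the aldo-keto reductase gene AKR1B10 at 21.1 ± 12.6 against 3.37 ± 0.73 TPM. Cholesterol and fatty acid synthesis genes rose as a list (median 0.18 over 33 members, camera in limma, adjusted p = 0.00283, and adjusted p = 0.520 with an estimated correlation). None of its members passed adjusted over the list alone, and sgRAC1 clone 1 stood at 0.04 against 0.21 and 0.41 in clones 2 and 3. The parental line and sgNTC clones 1 and 2 stood at 0.06, -0.12 and 0.05, so sgRAC1 clone 1 lay within the range of the RAC1-positive lines. Hypoxia and glycolysis genes rose as a list (median 0.20 over 32 members, camera in limma, adjusted p = 0.00839, and adjusted p = 0.505 with an estimated correlation). LDHA was at 1021 ± 27.0 against 780.0 ± 86.0 TPM, and no member passed adjusted over the list alone. The call was lost without sgNTC clone 1 for the cholesterol (camera in limma, adjusted p = 0.130), NRF2 (0.0811) and hypoxia (0.162) lists, and without sgRAC1 clone 3 for the cholesterol list (0.177). Nuclear oxidative phosphorylation genes fell as a list (median -0.08 over 33 members, camera in limma, adjusted p = 0.00447, and adjusted p = 0.435 with an estimated correlation). UQCRFS1 was at 54.4 ± 5.32 against 75.1 ± 12.9 TPM and no member passed adjusted over the list alone. The call was lost without sgRAC1 clone 1 (0.0556) or its replicate 1 (0.111). In batches 1 and 2 the medians were -0.15 and -0.04 for this list, 0.13 and 0.34 for cholesterol, 0.15 and 0.30 for NRF2 and 0.10 and 0.28 for hypoxia genes.

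Growth-related lists fell by small amounts. Cytosolic ribosomal protein genes fell as a list (median -0.12 over 50 members, camera in limma, adjusted p = 2.1e-07, and adjusted p = 0.456 with an estimated correlation). Lower members were 43, and 0 passed adjusted over the list alone. RPL27 was at 1425 ± 72.6 against 1680 ± 46.9 TPM. DNA replication genes fell as a list (median -0.12 over 41 members, camera in limma, adjusted p = 2.7e-04, and adjusted p = 0.505 with an estimated correlation). MCM4 was the 1 member past the threshold adjusted over the list alone, and GINS2 was at 56.6 ± 2.55 against 74.7 ± 3.33 TPM. Mitosis genes fell as a list (median -0.09 over 38 members, camera in limma, adjusted p = 0.00384, and adjusted p = 0.520 with an estimated correlation). CDC20 was at 232 ± 23.8 against 394 ± 81.6 TPM, and 0 members passed adjusted over the list alone. The mitosis median relative to the RAC1-positive lines was -0.02 in sgRAC1 clone 1, -5.75e-04 in clone 2 and -0.20 in clone 3, against -0.07 in the parental line and -0.04 and 0.10 in sgNTC clones 1 and 2. DNA replication genes stood at -0.10, -0.03 and -0.25 in clones 1, 2 and 3, against 0.07 in the parental line and -0.04 and -6.67e-04 in sgNTC clones 1 and 2. For both lists sgRAC1 clone 3 replicate 1 was the lowest knockout library and stood apart from the others. In batches 1 and 2 the medians were -0.16 and -0.02 for mitosis, -0.20 and -0.05 for DNA replication and -0.06 and -0.17 for ribosomal protein genes. The mitosis call was lost without sgRAC1 clone 3 (camera in limma, adjusted p = 0.264), its replicate 1 (0.153), sgNTC clone 2 (0.228), its replicate 1 (0.0782) or sgNTC clone 1 replicate 1 (0.0940). The YAP and TAZ call was lost without sgNTC clone 2 (camera in limma, adjusted p = 0.228), its replicate 1 (0.261), sgNTC clone 1 replicate 1 (0.140), sgRAC1 clone 1 (0.0524), its replicate 2 (0.0888), sgRAC1 clone 2 replicate 2 (0.0858) or sgRAC1 clone 3 replicate 2 (0.0978).

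**Figure D2:**
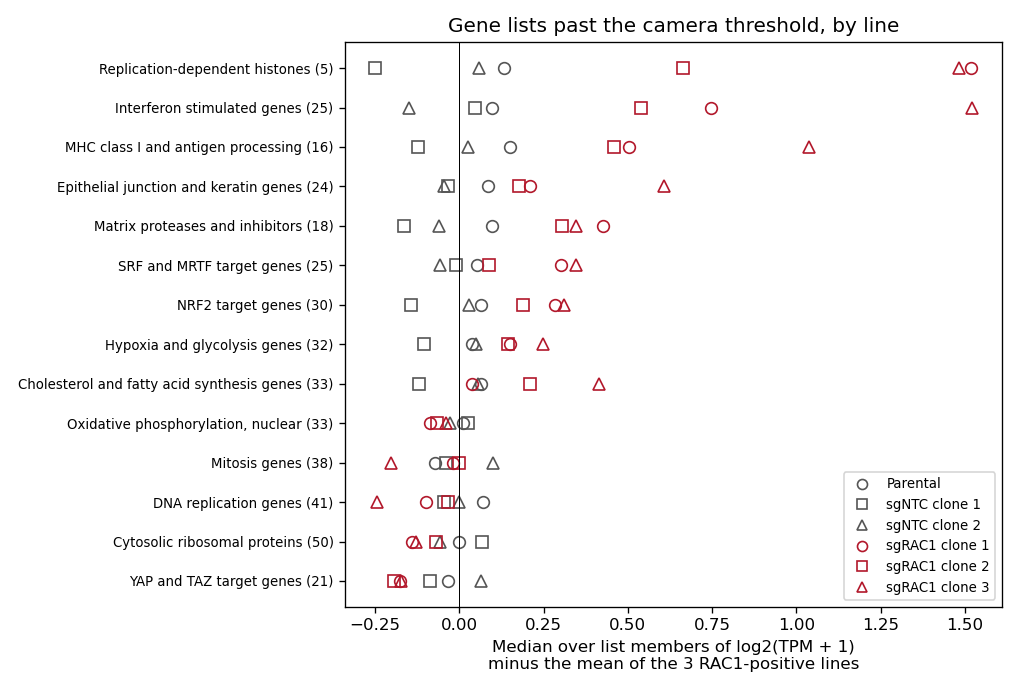
Median over the members of each of the 14 lists of log2(TPM + 1) minus the mean of the 3 RAC1-positive lines, 1 symbol per line, with the number of members in parentheses. For interferon stimulated genes the knockout clones lie at 0.75, 0.54 and 1.52 and the RAC1-positive lines between -0.15 and 0.10.

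The remaining lists did not pass, and each is given with its median log2 difference and camera's adjusted p in limma. EGFR family and ligand genes had a median of 0.24 (adjusted p = 0.0793). This list passed without sgNTC clone 2 replicate 1 (0.00823), without sgNTC clone 1 replicate 1 (0.0269) and with no level filter (0.0384). Rac effectors with the WAVE and Arp2/3 complexes were at 0.07 (adjusted p = 0.141), passing without sgNTC clone 2 replicate 1 (0.0293) or sgRAC1 clone 2 (0.0455). Target genes of p53 were at 0.05 (adjusted p = 0.191), passing without sgNTC clone 2 replicate 1 (0.0328). Rac exchange factors were at 0.09 (0.269) and Rac GAPs and GDIs at 0.11 (0.873). Semaphorins, plexins, ephrins and Eph receptors were at 0.29 (0.141), laminins and collagens of basement membrane at 0.12 (0.141), and growth factor ligands at 0.28 (0.141). Notch target genes were at 0.22 (0.161) and integrins and focal adhesion genes at 0.11 (0.275, and 0.0178 with no level filter). Mitochondrially encoded genes were at 0.06 (0.196, and 0.0118 without Parental replicate 1 or 0.0358 without sgRAC1 clone 3), and NF-kB and inflammatory genes at 0.20 (0.275, and 0.0424 without the parental line). Other receptor tyrosine kinases were at 0.15 (0.297) and ERK pathway target genes at -0.01 (0.297, and 0.0316 without sgNTC clone 2). Mesenchymal genes were at 0.16 (0.299), Wnt target genes at 0.04 (0.509) and TGF-beta target genes at 0.22 (0.814). Integrated stress and unfolded protein response genes had a median of 0.03 and a mean of -0.03 and were tested as lower (0.594), and housekeeping genes had a median of -0.05 and a mean of 0.01 and were tested as higher (0.672). Between batches 1 and 2 the median turned in sign for Rac effectors (-0.04 and 0.15), ERK targets (-0.11 and 0.01) and Wnt targets (-0.07 and 0.05). It also turned for integrated stress genes (-0.11 and 0.04) and housekeeping genes (-0.09 and 0.07). When adjusted over the list alone, 4 NF-kB genes were higher and 2 lower, and 4 housekeeping genes higher and 1 lower. By the same measure 3 laminin and collagen genes were higher and 1 lower, 2 Notch and 2 Wnt target genes and 1 mesenchymal gene higher, and 1 gene of the semaphorin list lower. No member of the other lists in this paragraph passed. With fry on the 12 libraries and the replicate number as a block, 5 of these lists passed, all as higher: laminins and collagens (fry in limma, adjusted p = 0.0185), growth factor ligands (0.0185), the EGFR family (0.030), semaphorins and ephrins (0.030) and other receptor tyrosine kinases (0.0371). That fit took libraries of 1 line as independent. With an estimated correlation in the same fit none of the 5 passed (camera in limma, adjusted p = 0.32 for each), nor did any pass with fry per line. NADPH oxidase genes had fewer than 3 members above the level filter and were not tested.

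Markers of other cell types were low. None of 10 fibroblast, 8 endothelial or 6 erythroid markers reached the level filter of 1 TPM in either genotype, and 1 of 12 immune markers did, CD14, at 0.277 to 3.26 TPM over the 6 lines. Of the neuroendocrine list 2 genes did, among them ENO2, also an enzyme of glycolysis, at 4.67 to 7.90 TPM in the RAC1-positive lines and 9.69 to 10.2 TPM in the knockout lines. Basal markers above the filter were 5, led by CD44, and luminal markers 4, led by STEAP1 at 41.9 to 128 TPM. No marker passed the limma test between genotypes.

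Each knockout clone was then set against the RAC1-positive lines, with p-values that measure the spread between libraries of a line. Genes called highest or lowest below are so only among those that met the symbol and level conditions of the naming rule. Other genes that passed could lie further out, as SDR16C5 (2.57) did above SCEL (2.42) in clone 2. In sgRAC1 clone 1, 84 genes passed in limma, 75 higher and 9 lower, and 70 higher and 18 lower with the replicate number as a block. The highest were the co-chaperone gene DNAJC12 at 32.7 against 0.544 TPM (log2 difference 4.39, SE 0.31, adjusted p = 7.3e-04) and the Wnt agonist gene RSPO3 at 21.5 against 0.703 TPM (3.77, SE 0.25, adjusted p = 7.3e-04), followed by CNTN1 (3.64). The fibrinogen chain gene FGB was at 4.43 against 26.2 TPM (-2.20, SE 0.23, limma adjusted p = 0.00892), RAC1 at -2.01 and CADM1 at -1.10. In sgRAC1 clone 2, 34 genes passed, 29 higher and 5 lower, and 18 with the replicate number as a block. Highest in clone 2 were the serpin gene SERPINB5 at 18.6 against 0.821 TPM (3.53, SE 0.32, limma adjusted p = 0.00671), TSPAN7 (3.24) and SCEL (2.42). Lowest in clone 2 were FMR1 (-2.07), MATN2 (-2.01) and the claudin gene CLDN11 (-1.95). In sgRAC1 clone 3, 188 genes passed, 161 higher and 27 lower, with SERPINB5 at 33.3 TPM (4.33, SE 0.32, limma adjusted p = 0.00105), TSPAN7 (3.67) and LGALS3BP (3.42) highest. Lowest in clone 3 were the glutathione transferase gene GSTP1 at 1.37 against 70.5 TPM (-4.93, SE 0.36, limma adjusted p = 0.00105), FMR1 (-2.69) and the collagenase gene MMP1 (-2.49). With the replicate number as a block, limma lost the calls of CADM1 in clone 1 (adjusted p = 0.0547), FMR1 (0.0574) and MATN2 (0.0534) in clone 2 and MMP1 in clone 3 (0.0682). These calls were lost under 11, 12, 10 and 13 of 15 alternatives. Leaving out single libraries gave 25 (without sgRAC1 clone 1 replicate 2) to 313 genes for clone 1, 13 (without sgNTC clone 1 replicate 1) to 185 for clone 2 and 28 (without sgRAC1 clone 3 replicate 1) to 670 for clone 3. Each maximum was reached without sgNTC clone 2 replicate 2, where that line is left with its library of 13608 genes.

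A set of 17 genes passed in the same direction in all 3 clones, RAC1 lower and 16 higher. Higher in clones 1, 2 and 3 were IFIT3, an interferon stimulated gene, by 1.73, 1.69 and 2.95 on the log2 scale. KYNU, an enzyme gene of tryptophan breakdown, was higher by 2.96, 2.39 and 2.71, and SERPINA1, which encodes alpha-1 antitrypsin, by 1.58, 1.56 and 2.23. These genes were picked as examples after their values were seen. Clones 1 and 2 shared 17 higher genes, clones 1 and 3 shared 44 and clones 2 and 3 shared 24, and the lower genes shared by these pairs were 1, 4 and 4. Equally long lists, ranked by limma's p, from 20 simulations of unchanged clones set against the same controls shared 3.4, 9.9 and 5.1 higher genes on average and at most 9, 16 and 8. For lower genes they shared 0.3, 1.1 and 0.9 on average and at most 1, 3 and 3, so the 1 lower gene of clones 1 and 2 was within the simulations. Independent lists of higher genes of these sizes would share 0.125, 0.695 and 0.269. Across 17367 genes, which are not independent replicates, the log2 differences of the clone pairs correlated at 0.47, 0.49 and 0.51, against 0.25 in 20 simulations of unchanged clones set against the same controls. Their covariances were 0.121, 0.139 and 0.140 against 0.0623, 0.0615 and 0.0607 simulated. All these simulations gave every line the same mean and every library the same spread for a gene. They leave out real differences between RAC1-positive lines, which enter the contrasts of all 3 clones. The overlap and correlation that shared controls alone can give may thus be understated, and the excess cannot be put down to the knockout. With one clone and its controls taken from batch 1 and the other clone and its controls from batch 2, which leaves 1 library per line, the correlations ran from 0.08 to 0.16.

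The RAC1-positive lines were compared with each other by the same limma fit as a background. Between sgNTC clone 1 and the parental line 0 genes passed (508 at unadjusted p under 0.05) and between the sgNTC clones 0 passed (1322 at unadjusted p under 0.05). In sgNTC clone 2 against the parental line 2 genes passed, both lower: KYNU at 0.895 against 11.01 TPM (-2.66, SE 0.20, limma adjusted p = 0.00785) and the protease-activated receptor gene F2RL1 at 5.24 against 30.2 TPM (-2.32, SE 0.22, limma adjusted p = 0.0248). With no level filter limma called 12 genes for sgNTC clone 1 against the parental line, 4 for sgNTC clone 2 against the parental line and 11 between the sgNTC clones, where median-of-ratios scaling called 1. The calls of KYNU and F2RL1 were lost under 6 and 8 of 15 alternatives. KYNU, higher in all 3 knockout clones, thus also differed between RAC1-positive lines. Without sgNTC clone 2 replicate 1, limma called 22 genes for sgNTC clone 2 against the parental line and 24 for sgNTC clone 1 against clone 2, and without replicate 2 of that clone it called 1829 and 2351. The former count was 1 without either library of sgNTC clone 1 and 0 without either library of the parental line, of sgRAC1 clone 1 or of sgRAC1 clone 3.

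The clone made with the guide sgRAC1_1 was compared with the 2 clones made with sgRAC1_2. GSTP1 was higher in sgRAC1 clone 1, at 51.0 against 8.98 TPM (3.06, SE 0.38, limma adjusted p = 0.0424), as were RSPO3 (2.96) and DNAJC15 (2.74). Lower were ENPP5 at 0.161 against 10.9 TPM (-3.25, SE 0.30, limma adjusted p = 0.00912), SERPINB5 (-3.25) and FGB (-3.01). Higher and lower here mean against clones 2 and 3 only. In the RAC1-positive lines GSTP1 was at 70.5 TPM, RSPO3 at 0.703, SERPINB5 at 0.821 and FGB at 26.2 TPM. Clone 1 was thus not above these lines in GSTP1, nor below them in SERPINB5, which was at 1.78 TPM in clone 1 and 25.9 TPM in clones 2 and 3. In all 15 genes passed in limma, 11 higher and 4 lower, and 8 with the replicate number as a block, where GSTP1 missed the threshold (limma adjusted p = 0.0883). With no level filter 67 genes passed (53 higher, 14 lower). The calls of GSTP1 and SERPINB5 were lost under 10 and 8 of 15 alternatives. As sgRAC1_1 has a single clone, guide and clone cannot be told apart. The count was 24 without either library of sgNTC clone 2, 9 without either library of sgRAC1 clone 1 or without sgRAC1 clone 3 replicate 2, and 7 and 8 without replicates 1 and 2 of sgRAC1 clone 2.

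Genes near RAC1 and on chromosome 9 were examined by position after their values had been seen, using 6812 protein-coding genes of at least 5 TPM, with the median over these genes subtracted in each line. The 19 genes telomeric of RAC1 (chromosome 7, 497258 to 6348981, GRCh38) had a median log2 difference from the RAC1-positive mean of -0.69 in sgRAC1 clone 1, -0.37 in clone 2 and -0.49 in clone 3. It was 0.08, -0.05 and -0.05 in the parental line and sgNTC clones 1 and 2. Of these genes 14 were below the RAC1-positive mean in all 3 clones. The 4 nearest RAC1 went both ways: EIF2AK1 was at -0.05, 0.29 and 0.29 in clones 1, 2 and 3, PMS2, which has near-identical copies, at 0.02, 0.22 and -0.12, FAM220A at -0.26, 0.11 and -0.11, and AIMP2 at -0.65, 0.0039 and -0.38. PDGFA, nearest the tip, was at -0.06, 0.23 and 0.31. The next 19 genes on the centromeric side (6409126 to 19709087) had medians of -0.24, -0.04 and -0.44 in clones 1, 2 and 3. On the long arm of chromosome 9 (65668805 to 137590490) 215 genes had medians of 0.02 in clone 1, -0.32 in clone 2 and -0.27 in clone 3. On the short arm 83 genes had 0.03, 0.01 and 0.12. Replicates 1 and 2 gave -0.76 and -0.62 in clone 1, -0.44 and -0.29 in clone 2 and -0.53 and -0.38 in clone 3 for the genes telomeric of RAC1. For the long arm of chromosome 9 they gave -0.34 and -0.33 in clone 2 and -0.27 and -0.28 in clone 3.

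**Figure D3:**
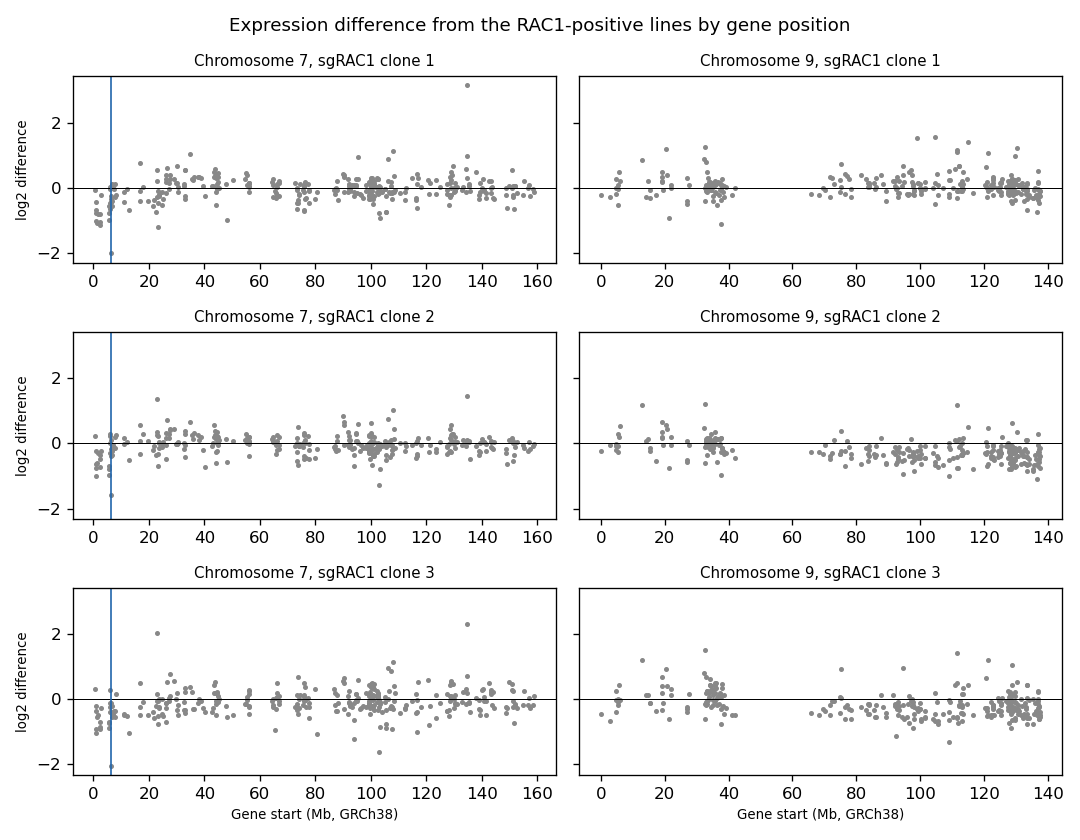
Log2 difference from the mean of the RAC1-positive lines against gene start in Mb (GRCh38) for chromosomes 7 and 9 in the 3 knockout clones, 1 point per gene, with a vertical line at RAC1. The 19 genes telomeric of RAC1 have medians of -0.69, -0.37 and -0.49, and the long arm of chromosome 9 has 0.02, -0.32 and -0.27, in clones 1, 2 and 3.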

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

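None of the tests in this part was chosen after its result was seen.

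In 96 groups of 6 libraries (the levels of named genes, the medians of called lists and library measures, per genotype) the gap between an extreme library and its nearest neighbour was set against the range of the group, and 9 groups held a library that stood apart, where chance gives about 4.8. sgNTC clone 2 replicate 1 was lowest of the RAC1-positive libraries in its median correlation with the other libraries (0.872, gap 0.810 of the range) and in RAC2 (2.02 TPM, gap 0.627 of the range). sgNTC clone 2 replicate 2 was lowest in DDX58 (2.76 TPM, gap 0.679 of the range). Parental replicate 2 was highest in DIMT1 (183 TPM, gap 0.657 of the range) and in DNAJC2 (71.2 TPM, gap 0.734 of the range). Parental replicate 1 had the lowest share of TPM from ribosomal RNA loci among the RAC1-positive libraries (4.43%, gap 0.644 of the range). Among the knockout libraries, sgRAC1 clone 3 replicate 1 was lowest in the median of DNA replication genes (gap 0.693 of the range), in the median of mitosis genes (gap 0.863 of the range) and in its median correlation with the others (0.936, gap 0.631 of the range).

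In the limma contrast of sgRAC1 clone 1 with clones 2 and 3, 15 genes passed, and the 3 largest in each direction that met the naming rule are given, so that they differ follows from how they were picked. The difference was 3.06 for GSTP1, 2.96 for RSPO3, 2.74 for DNAJC15, -3.25 for ENPP5, -3.25 for SERPINB5 and -3.01 for FGB on the log2 scale, with adjusted p from 0.00912 to 0.0424. With the replicate number as a block GSTP1 missed the threshold (limma adjusted p = 0.0883).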

How the results depend on the processing

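Chosen only after the data were seen were the tests without each single library for the comparison of genotypes and for the lists, the random block fit less sgNTC clone 2 replicate 1, the lists with synonyms matched, the estimated correlation and fry with the replicate block, and the count of genes over other splits of the lines.

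The count of 1 gene between genotypes moved with the unit of replication. Over 12 libraries limma called 334 genes with no block, 343 with the replicate block, 369 with the line as a random block, 320 with both blocks, and 620 with the line as a random block less sgNTC clone 2 replicate 1. With 1 value per line it called 0 genes under median-of-ratios scaling, upper quartile scaling, no level filter, batch 1 alone and pseudocount 0.1, 2 at pseudocount 5, 3 at a mean of at least 5 TPM, 33 in batch 2 alone, and 0 to 21 without single lines or libraries. Fewer units may explain part of the lower counts per line, but neither this nor the cause of the other shifts was tested.

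The difference in RAC1 kept its sign throughout. It missed the threshold at -1.89 under median-of-ratios scaling (limma adjusted p = 0.0578), -1.91 under upper quartile scaling (0.0605), -1.89 with no level filter (0.172, with more genes tested), -1.93 in batch 1 alone (0.128) and -1.91 at pseudocount 0.1 (0.0857), and ran from -2.04 to -1.80 without single lines or libraries, with adjusted p from 0.0201 to 0.370. Small differences of genes that were not called turned in sign: RHOG was at 0.10 in batch 1 and -0.13 to 0.11 without single lines or libraries, CDC42 at 0.25 in batch 2 and -0.16 to 0.0098, and VAV2 at 0.14 in batch 1 and -0.29 to 0.092, and the cause was not tested. Of the other values for named genes, 2485 kept their side of the threshold and 278 passed it where the test per line did not.

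The 14 lists fell to 0 with an estimated correlation, 0 with fry and 0 with an estimated correlation and the replicate block, and fry with the replicate block called 13, of which 8 were among the 14. Both fits with the replicate block took libraries of 1 line as independent. Lists that were not called changed direction in places: integrated stress genes with fry (adjusted p = 0.950), TGF-beta target genes with synonyms matched (0.873), and, without single lines or libraries, mitochondrially encoded genes (0.0118 to 0.673), Wnt target genes (0.155 to 0.998), integrated stress genes (0.103 to 0.985), housekeeping genes (0.442 to 0.985), TGF-beta target genes (0.465 to 0.991) and Rac GAPs and GDIs (0.520 to 0.998), and the cause was not tested.

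Without single libraries, the count was 25 to 313 genes for sgRAC1 clone 1, 13 to 185 for clone 2 and 28 to 670 for clone 3, 0 to 1829 for sgNTC clone 2 against the parental line, 0 to 2351 between the sgNTC clones and 7 to 24 between the guides. A line left with 1 library was assumed to vary like the other lines. With the replicate block clone 2 had 18 genes (16 higher, 2 lower), the guides 8 (5 higher, 3 lower), and the lower genes of clone 1 went from 9 to 18. The block moved no other count of these comparisons, in total or by direction, by over 1.5 times. Of 390 values for the genes named for them, 290 kept the call and 100 lost it, 5 of these with the block. With no level filter, 12 genes passed for sgNTC clone 1 against the parental line, 4 for sgNTC clone 2 against the parental line, 11 between the sgNTC clones and 67 between the guides, and 1 between the sgNTC clones under median-of-ratios scaling. The authors' deposited table had 893 genes at adjusted p 0.01 and 358 at adjusted p 0.05 with an absolute log2 fold change of at least 1.

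The 6 lines can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene and 14 lists, 1 of the 10 splits in each case, and the highest of the other splits gave 0 genes and 13 lists, the latter with the parental line and sgRAC1 clones 1 and 3 on one side. DESeq2 on line sums was not run, as the values are not counts. The depth of each library is unknown, so what it limits is not given per library. sgNTC clone 2 replicate 1 had 12843 genes at 1 TPM or more, against 15535 to 16356 in the others, and correlated at 0.860 with the other library of its line, against 0.9465 to 0.953 in the other lines.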

Other observations

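Chosen only after the result was seen were the 2 tests on the genes telomeric of RAC1 that concern the sgNTC clone 2 library and the loss of a copy, the bootstrap intervals and how they were held to the bounds, the change of the medians without that library, and the genes named in the next paragraph.

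Other genes that passed in limma in each of the 3 knockout clones were higher in all of them. CDH3, which encodes P-cadherin, was higher by 1.60, 1.46 and 2.43 on the log2 scale in clones 1, 2 and 3, SCEL, a gene of the cornified envelope, by 1.85, 2.42 and 2.34, and SDR16C5, a retinol dehydrogenase gene, by 1.73, 2.57 and 3.30. MLLT11 was higher by 1.37, 1.69 and 1.81, NCOA7 by 1.60, 1.13 and 1.17, and SQRDL, a mitochondrial sulfide oxidation gene, by 0.64, 0.97 and 1.14. The histone genes HIST2H2AA3 and HIST2H2AA4 were higher by 2.35 and 2.34 in clone 1, 1.15 and 1.14 in clone 2, and 1.92 and 1.91 in clone 3, but they are near-identical copies and count as 1 signal.

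The lower level of the 19 genes telomeric of RAC1 was weighed first. The tables argued against GC content and transcript length, since after regression on both the medians stayed at -0.345 or lower in the 3 clones, with an interval in clone 2 of -0.665 to -0.202. They also argued against the sgNTC clone 2 replicate 1 library as the source, since without it the medians moved away from 0. They went from -0.69, -0.37 and -0.49 to -0.73, -0.442 and -0.57 in clones 1, 2 and 3, and the intervals of the change ended at 0.144 or less. The interval of the median itself in clone 2 without that library was -0.758 to -0.0926. That interval reached past the bound set for this cause, so it alone could not decide. The 4 genes nearest RAC1, picked after their values were seen, had medians of -0.15, 0.163 and -0.11 in clones 1, 2 and 3. In clone 2 (interval 0.00389 to 0.291) this goes against loss of a copy from RAC1 to the tip. Such a loss stays open in clones 1 and 3, with intervals of -0.655 to 0.0242 and -0.377 to 0.292. In clones 1 and 3 the next 19 genes on the centromeric side were also lower, with medians of -0.24 and -0.44. A loss that ends at RAC1 would not by itself give that. Loss of a shorter segment was not tested. An effect of RAC1 loss on these genes stays open and was not tested, and DNA copies were not analysed here.

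The lower level of genes on the long arm of chromosome 9 in sgRAC1 clones 2 and 3 was weighed next. GC content and transcript length were argued against, since the medians after regression were -0.308 and -0.295, with intervals that ended at -0.279 and -0.228. Loss of a copy of the arm may be the source, as the more and the less expressed genes were both lower in both clones, the smallest difference being -0.210 with an interval of -0.277 to -0.165, but any cause that acts on the whole arm would give this too. The median in clone 1 was 0.02, so the pattern was not shared by all knockout clones, and whether it goes with the guide sgRAC1_2 was not tested. VAV2 lies on this arm, at 3.28, 1.498 and 2.44 TPM in clones 1, 2 and 3 against 2.68, 1.99 and 3.28 TPM in the parental line and sgNTC clones 1 and 2.

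The higher level of interferon stimulated and MHC class I genes, 41 in all, was weighed last. Local copy number was argued against, since the medians stayed at 0.502 or more after the median of the 40 nearest expressed genes was subtracted. A rise common to all transfected and cloned lines was also argued against. The medians of sgNTC clones 1 and 2 minus the parental line were -0.143 and -0.129, against 0.607 in the knockout clones. A rise that differs from clone to clone stays open, as only 2 clones of 1 non-targeting guide were compared. The sgNTC clone 2 replicate 1 library was argued against as the source, since without it the medians moved from 0.67, 0.52 and 1.19 to 0.58, 0.4665 and 1.18 in clones 1, 2 and 3, and the intervals started at 0.258 or higher. Loss of RAC1 might raise these genes, which stays a hypothesis, as the list tests did not pass with an estimated correlation (adjusted p = 0.435) and each genotype has 3 lines.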
